A study of Homo sapiens with 6 samples.

How the data were processed

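Gene expression was measured by RNA sequencing in 6 libraries of BEAS-2B cells, 3 pretreated with medium (control) and 3 with ZQ, all collected after MRSA was added. Per the labels' protocols, TRIzol-extracted RNA was treated with DNase and made into libraries with an NEBNext Ultra kit. The deposited table holds raw read counts per gene, not normalised, for 60892 rows. Per the submitters' processing notes, the genome build was GRCh38 and Cufflinks 2.1.1 was among the tools, with no role given. The aligner, the counting tool, the annotation and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. A symbol was matched to 60463 rows by Ensembl ID, and 228 carry other IDs without coordinates, which took 0.099% of counts in control and 0.141% in ZQ libraries.

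Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), scaled by TMM and tested with the quasi-likelihood F-test of ZQ against control, with Benjamini-Hochberg adjustment over all 12994 tested genes and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM values are scaled by TMM factors unless library totals are named. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01, as a family of 38 lists with at least 5 tested members out of 41 fixed. An estimated correlation and fry were computed beside it. Camera compares a list with the other tested genes, whereas fry tests its members alone and so passes more easily where many genes changed. Each list also has the count of members past the threshold over all genes and adjusted over the list alone. Alternatives used DESeq2 1.42.0, limma-voom, other scalings and filters, a replicate block and each library left out.

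The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names 29 key genes whatever their value, the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between groups, and up to 4 members per list with the smallest adjusted p. A gene with no count in a group has its fold computed against a floor of 3 counts over the group, and with 1 to 3 counts a ratio with a 95% exact binomial counting interval. Leukocyte markers, differentiated airway markers and non-polyadenylated small RNA genes had 2 tested members each and were not tested as lists.

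GC content, transcript and exon length, positions and protein sequences came from GENCODE release 29 on GRCh38. Offsets for GC content and transcript length were smooth curves fitted per library with mgcv 1.9.3. Those offsets, control libraries thinned to the ZQ depth, a weight per group, a stricter filter and the comparison of rises with the density on olfactory receptor genes were chosen after seeing the data. The fit was tested on simulated data: counts drawn for the tested genes of this comparison, with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 6% of the 2-fold and 39% of the 4-fold changes, so power for single genes was low in that setting. With so few genes changed, the adjusted threshold is stricter than in the data, where 4978 genes passed. These shares therefore do not give the power of the comparison itself. The filter kept 11842 genes there, and any changed gene it left out counted as not recovered. Of the 50 calls of the fit 5 were false, which is 10% and above the nominal 5%, though these calls come from a single run. Both groups were drawn with the same spread for each gene, unlike the data, so false calls at unequal spread were not measured. The recovery first required of the test was higher than what was reached, and the requirement was then changed to unbiased folds with some recovery. Median fitted sizes were 1.04 and 2.00 on the log2 scale for simulated 1 and 2. The list test called 0 of 38 unchanged lists. Genes were drawn independently there, so this does not measure false list calls where genes are correlated, as they may be in the data. On counts simulated with a GC trend alone, the offsets took 2363 calls to 0. No gene was changed and no length trend was put in there. That run therefore cannot show whether the offsets also remove true effects of ZQ that follow GC content or length.

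Depth differed 5.95 times between groups, and 3 counts in a single library are 0.204 to 0.257 CPM in a control and 1.22 to 1.45 CPM in a ZQ library, by library totals without TMM factors. The biological coefficient of variation was 0.265 in control and 0.522 in ZQ libraries, and its common estimate over all 6 libraries was 0.379.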

Results

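RNA was sequenced from BEAS-2B cells, an immortalised human bronchial epithelial line, after contact with methicillin-resistant Staphylococcus aureus (MRSA), an antibiotic-resistant bacterial cause of pneumonia. The control group received medium for 24 hours before the bacteria, and the ZQ group received ZQ at 10 mg/mL for the same time. ZQ stands for Zhenqi Granules, a herbal preparation. Cells of both groups were collected 2 hours after MRSA was added, at 1 bacterium per cell. There were 3 libraries per group and no group without bacteria, so the data compare ZQ with medium in infected cells and hold no measure of the response to MRSA itself. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

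Control libraries held 11665967 to 14699677 counts and ZQ libraries 2064566 to 2451746, a mean depth 5.95 times lower. Despite the lower depth, more genes had a count with ZQ, 23836 to 24713 against 19400 to 21141 in the control libraries. Transcripts of the mitochondrial genome took 39.6% ± 1.13 of counts (SD, n = 3) with ZQ and 8.74% ± 1.57 (SD, n = 3) in control cells. The 10 most abundant genes took 37.8% ± 1.1 against 10.5% ± 1.33 of counts (SD, n = 3 each). In each of these measures the groups did not overlap, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries can give. Log2 CPM correlated across genes at 0.968 to 0.982 between control libraries, at 0.802 to 0.812 between ZQ libraries and at 0.698 to 0.714 between groups, where genes are not independent replicates.

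**Figure D1:**
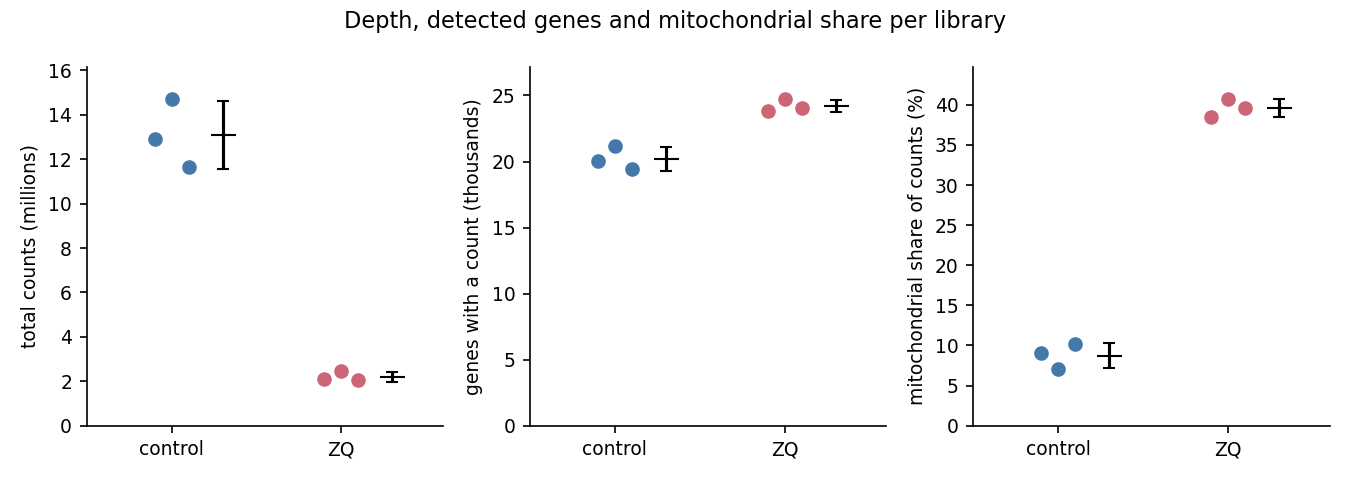
Total counts, genes with at least 1 count, and the percent of counts on mitochondrially encoded genes, with 1 point per library and bars for mean ± SD (n = 3 per group). ZQ libraries held 2064566 to 2451746 counts against 11665967 to 14699677, and their mitochondrial share was 39.6% against 8.74%.

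The series asks whether ZQ lowers endoplasmic reticulum (ER) stress and the inflammatory response of infected airway cells. HSPA5, which encodes BiP, the main ER-lumen chaperone, fell from 1832 ± 277 to 122 ± 8.71 CPM (SD, n = 3 each), a log2 change of -3.91 ± 0.15 (SE, edgeR adjusted p = 2.4e-07). The calnexin gene CANX fell as far, with a log2 change of -3.9 ± 0.29, and PDIA3, a disulfide isomerase of the ER, changed by -3.18 ± 0.19. With offsets for GC content and length HSPA5, CANX and PDIA3 stood at -3.47, -3.00 and -2.48. In contrast, ATF4, a transcription factor of the integrated stress response, rose with a log2 change of 1.21 ± 0.16 (0.79 with offsets for GC content and length), and DDIT3, which encodes the stress-induced factor CHOP, rose by 1.9 ± 0.30 on the log2 scale. Secreted mediators went both ways and did not pass as a list (camera adjusted p = 0.49). The chemokines CXCL1, CXCL3 and CCL2 fell with log2 changes of -2.08 ± 0.32, -2.38 ± 0.48 and -1.91 ± 0.19, IL32 and CSF2 rose by 2.65 ± 0.31 and 1.65 ± 0.49 on the log2 scale, and IL6 stood at 5.28 ± 1.50 CPM in control and 5.48 ± 2.82 CPM in ZQ cells (SD, n = 3 each).

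Over all genes, 12994 were tested and 4978 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, of which 2506 were higher and 2472 lower with ZQ. The groups did not overlap in 6947 of the 12994 tested genes, or 53.5%, where chance alone separates 3 against 3 libraries in 10% of genes. The split depended on scaling, with 3767 higher and 1611 lower under upper-quartile scaling and 1785 higher and 3503 lower by library totals. Those scalings moved the median change of the same genes by 0.45 and -0.38 on the log2 scale, and without a low-count filter the split was 7957 to 3646. Leaving out control replicate 1 gave 2815 genes and leaving out control replicate 3 gave 3055. Of the genes called, 288 had no count in any control library and 38 none in any ZQ library. Of 2448 genes called higher with an annotated length, 1203, or 49.1%, held no more ZQ counts per kb than the 99th percentile of olfactory receptor genes (16.0), which airway cells are not known to use. Pooled over those receptor genes the density was 1.50, so this percentile is a loose upper limit for background. The same share was not computed for all tested genes or for those called lower, so whether 49.1% is particular to the rises is not known. Background reads may account for part of the rises, and how large a part was not measured. Fold changes also followed GC content, with a Spearman rho of 0.514 across 9206 protein-coding genes, and transcript length, with a rho of -0.22. The fifth of genes lowest in GC had a median log2 change of -1.08 and the fifth highest in GC 0.73. Offsets per library for GC content and transcript length, chosen after seeing the data, gave 4226 genes (2216 higher, 2010 lower), of which 3071 were among the 4978 and 3006 of those had the same direction.

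**Figure D2:**
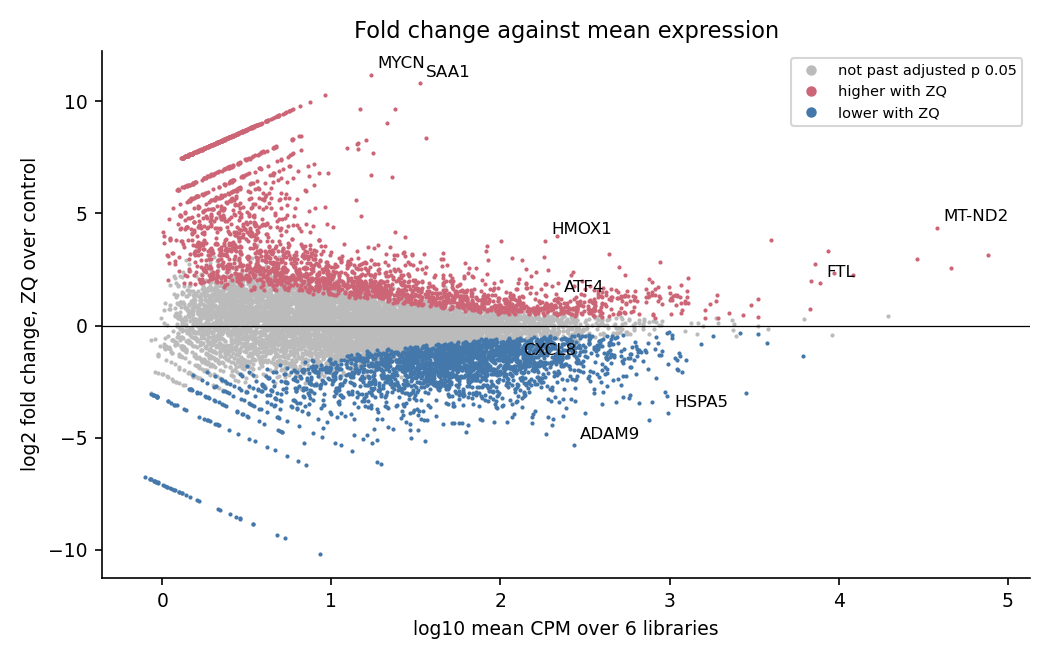
Log2 fold change of ZQ over control against log10 mean CPM for the 12994 genes tested, coloured by direction where the edgeR adjusted p was under 0.05. Of these, 2506 were higher and 2472 lower, and the upper diagonal streaks are genes with few or no counts in control cells.

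**Figure D3:**
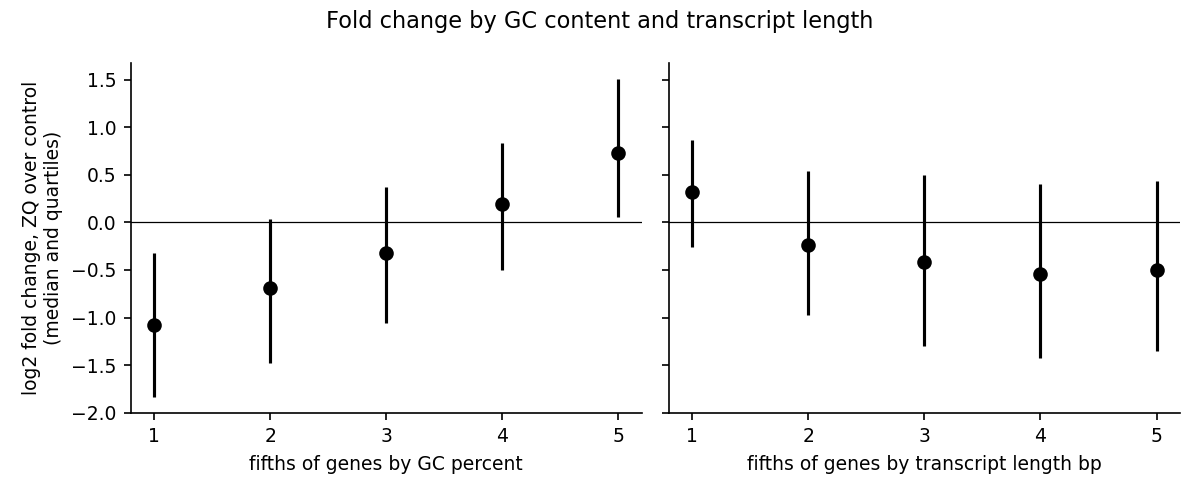
Median and quartiles of the log2 fold change of ZQ over control in 5 equal-sized bins of 9206 protein-coding genes ordered by GC content (left) and transcript length (right), lowest first. The median rises from -1.08 to 0.73 over the GC bins.

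The ER chaperone list, folding enzymes known to be induced through ATF6, had 12 of 20 tested members lower and 0 higher, or 15 lower adjusted over the list alone. Its median log2 change was -1.66 (camera adjusted p = 8.7e-05 with the preset correlation, adjusted p = 0.13 with an estimated correlation). PDIA4, another disulfide isomerase, fell with a log2 change of -2.62 ± 0.19, and HERPUD1, which acts in ER-associated degradation, with one of -1.48 ± 0.21 (edgeR adjusted p = 1.2e-05 and 5.0e-04). ATF6 itself, the ER stress sensor, changed by -2.21 ± 0.61 (edgeR adjusted p = 0.016), a call that ended without control replicate 1 (-1.96) and with the GC and length offsets (-1.63), and the change was -3.34 without ZQ replicate 3. The list of XBP1 targets and ER-associated degradation had 15 members lower and 3 higher of 28, or 16 and 4 adjusted over the list alone, with a median of -1.17 (camera adjusted p = 0.0024, adjusted p = 0.13 with an estimated correlation). With the offsets its median was -0.76, with 12 lower and 3 higher. SEL1L, a scaffold of the degradation complex, fell with a log2 change of -4.73 ± 0.37, and TRAM1, a translocon partner, with one of -2.39 ± 0.19, or -0.95 with the offsets. XBP1 had a log2 change of 0.55 ± 0.20 (edgeR adjusted p = 0.057) and passed in 6 of 18 alternatives, that without control replicate 3 (0.79) among them, and DNAJB9, an ER co-chaperone, one of -1.52 ± 0.63 (edgeR adjusted p = 0.080). ZQ replicate 2 held 86 of the 111 ZQ counts of DNAJB9, whose change was -3.04 and passed without that library, was -0.36 with the offsets, and passed in 6 of 18 alternatives. In GRCh38 the HSPA5 gene lies on chromosome 9 at 125234853 to 125241330, ATF4 on chromosome 22 at 39519695 to 39522685 and DDIT3 on chromosome 12 at 57516588 to 57521737.

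The ATF4 arm went both ways, with 5 of 29 members higher and 5 lower over all genes and also adjusted over the list alone (median 0.08, camera adjusted p = 0.87). Without a low-count filter it passed as lower (median -0.18, camera adjusted p = 0.039), among tested genes whose median log2 change was 1.75. Beside ATF4 and DDIT3, CEBPB, a transcription factor of stress and inflammation, rose by 2.73 ± 0.41 on the log2 scale (1.33 with the offsets), while SLC3A2, an amino acid transporter subunit, changed by -1.6 ± 0.17. TRIB3, a target of CHOP, had a log2 change of 0.90 ± 0.36 (edgeR adjusted p = 0.072), passed in 6 of 18 alternatives, those without control replicate 2 (1.24) and without ZQ replicate 3 (1.06) among them, and stood at 0.54 without ZQ replicate 2 and -0.28 with the offsets. ASNS, asparagine synthetase, held 7 counts in control and 2 in ZQ libraries and was not tested. The mean log2 CPM of the ATF4 arm minus that of the ER chaperones was -2.42 ± 0.31 in control and -0.66 ± 0.18 in ZQ libraries (SD, n = 3 each), a shift of 1.76 with an exact two-sided permutation p of 0.1, the smallest possible. Of 18 cytosolic tRNA synthetases, several of which ATF4 induces, 11 were lower and 1 higher over all genes and adjusted over the list alone (median -0.75, camera adjusted p = 0.011, adjusted p = 0.18 with an estimated correlation). EPRS1, the glutamyl-prolyl synthetase, fell with a log2 change of -2.28 ± 0.24. The list call ended with the GC and length offsets (median -0.62) and with controls thinned to the ZQ depth (median -0.52), both chosen after seeing the data.

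**Figure D4:**
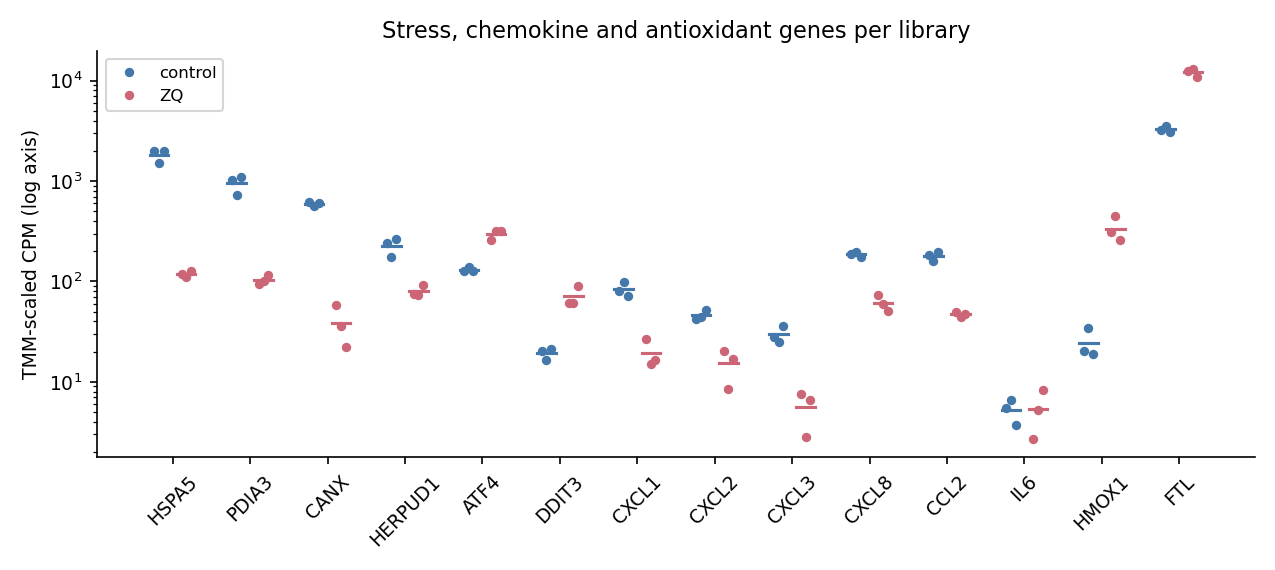
TMM-scaled CPM on a log axis for ER stress, chemokine and antioxidant genes, with 1 point per library and a line at each group mean (n = 3 per group). HSPA5 fell from 1832 to 122 CPM, whereas DDIT3 stood at 19.4 CPM in control and 72.2 CPM in ZQ cells.

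Of 19 tested cytokine and chemokine genes, 5 were lower and 2 higher over all genes and adjusted over the list alone, and the list did not pass its test (camera adjusted p = 0.49), though it passed as lower by fry (adjusted p = 0.035) and without a low-count filter (adjusted p = 0.028). Without that filter the 38214 genes tested had a median log2 change of 1.75, so a call as lower there need not mean a fall. The median of the list, 0.05, and its mean of -0.21 differ in sign, and leaving out 1 library moved the median from -0.62 (without ZQ replicate 3) to 0.58 (without control replicate 1). The neutrophil chemokine CXCL8 went from 187 ± 11.3 to 62.0 ± 11.4 CPM (SD, n = 3 each), a log2 change of -1.59 ± 0.20 (edgeR adjusted p = 2.7e-04). With the GC and length offsets the CXCL8 change was -0.04 ± 0.24 and the call ended, while CXCL1, CXCL3 and CCL2 stayed at -1.92, -2.09 and -1.46. The GC content of CXCL8 is 33.4%, near the lowest of the protein-coding genes binned by GC (31.8%), against 45.6% for CXCL1 and 44.7% for CXCL3. Its corrected value therefore depends on the low end of the fitted curve. CXCL2 had a log2 change of -1.58 ± 0.39 (edgeR adjusted p = 0.0091), which missed the threshold without control replicate 3 (-1.34). IL32, a proinflammatory cytokine, rose by 2.65 ± 0.31 on the log2 scale (1.66 with the offsets). CSF2, the granulocyte-macrophage growth factor, had a log2 change of 1.65 ± 0.49 (edgeR adjusted p = 0.023) and lost its call in 7 of 18 alternatives, among them those without control replicate 1 or 2 and without ZQ replicate 1 or 2. No call was made for IL1B (log2 change 0.61, or 1.03 with the offsets and 0.37 without ZQ replicate 2), IL1A (0.51, or 1.68 with the offsets and -0.78 without ZQ replicate 3) or IL6 (0.05, or 0.52 with the offsets). CCL20, with 77 control counts and 6 ZQ counts, all 6 in ZQ replicate 3, had no call (-0.68) but was called lower without that library. PTGS2, a prostaglandin synthase, had 80 control counts and 3 ZQ counts, all 3 in ZQ replicate 3, 3.38-fold lower with a 95% counting interval of 1.12 to 16.7 and no call. TNF had 1 count in control and 0 in ZQ libraries and was not tested. The CXCL8 gene lies on chromosome 4 at 73740506 to 73743716 (GRCh38). The genes CXCL1, CXCL2 and CXCL3 are near-identical neighbours on chromosome 4, so reads may have been shared between them.

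Of 25 NF-kB signalling genes, 4 were higher and 5 lower over all genes and adjusted over the list alone (median -0.40, camera adjusted p = 0.69). NFKB2, a subunit of the non-canonical pathway, and the inhibitor NFKBIE rose by 2.97 ± 0.39 and 3.21 ± 0.42 on the log2 scale, and TNFAIP8 fell, with a change of -2.47 ± 0.40 (-1.49 with the offsets). The feedback inhibitors NFKBIA and TNFAIP3 and the adhesion gene ICAM1 had log2 changes of -0.40, -1.22 and -1.36 without passing (edgeR adjusted p = 0.083, 0.10 and 0.15), and passed in 4, 4 and 2 of 18 alternatives, NFKBIA with the offsets and without ZQ replicate 2 among them (-0.63 each), while it stood at -0.24 without control replicate 1. Control replicate 2 held 1247 of the 2009 control counts of TNFAIP3 and 571 of the 883 of ICAM1, and without it the changes were -0.51 and -0.56. TNFAIP3 passed without ZQ replicate 2 (-1.84) and ICAM1 without ZQ replicate 1 (-2.28). Among 19 pattern recognition genes, 5 were higher and 3 lower over all genes and adjusted over the list alone (median -0.13, camera adjusted p = 0.72), with the kinase IRAK1 up by 2.20 ± 0.23 on the log2 scale (1.13 with the offsets). TLR2, which senses staphylococcal lipoproteins, held 26 counts in control and 5 in ZQ libraries and was not tested. CD14, a co-receptor, had 217 control counts and 1 ZQ count, 27.5-fold lower with a 95% counting interval of 4.89 to 1092.

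Interferon-stimulated genes went both ways, with 6 of 37 higher and 10 lower over all genes and adjusted over the list alone (median -0.65, or -0.38 with the offsets, camera adjusted p = 0.24). The list passed as lower by fry (adjusted p = 0.039), which does not compare it with other genes. It also passed as lower in camera without a low-count filter (adjusted p = 3.8e-05). There the 38214 genes tested had a median log2 change of 1.75, so that call need not mean a fall. IFI27 and the antiviral membrane protein gene IFITM3 rose by 3.2 ± 0.19 and 1.71 ± 0.11 on the log2 scale (2.03 and 0.74 with the offsets), and IFIT3 fell, with a change of -2.29 ± 0.29. ISG15, a ubiquitin-like modifier, rose by 1.48 ± 0.17 on the log2 scale, but stood at -0.37 with the offsets and lost its call. Class I antigen presentation genes had 4 of 16 higher and 3 lower, or 5 and 3 adjusted over the list alone (median 0.60, camera adjusted p = 0.63). With the offsets 2 were higher and 2 lower, and the median was -0.07, while without ZQ replicate 2 it was 0.26. The antimicrobial and complement list had 2 of 7 higher and 3 lower over all genes and adjusted over the list alone (median -0.65, mean 0.91, camera adjusted p = 0.70), with a median near -1 without ZQ replicate 1, and passed as higher by fry (adjusted p = 0.0031). SAA1, an acute-phase protein gene, had 1 count in control and 380 in ZQ libraries, a ratio of 2997 with a 95% counting interval of 535 to 118676. Complement C3 rose by 4.19 ± 0.46 on the log2 scale, and the complement regulator CD46 fell, with a change of -4.30 ± 0.30. The SAA1 gene, on chromosome 11 at 18266174 to 18269977 (GRCh38), has a near-identical paralog with which reads may be shared. Immediate early genes had 6 of 36 higher and 4 lower, or 5 and 4 adjusted over the list alone (median 0.13, camera adjusted p = 0.70), and with the offsets 4 higher and 5 lower (median -0.29).

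HMOX1, which degrades haem and is a classic NRF2 target, rose from 24.7 ± 8.43 to 342 ± 97.9 CPM (SD, n = 3 each), a log2 change of 3.79 ± 0.30 (edgeR adjusted p = 1.7e-05). The ferritin genes FTL and FTH1 rose by 1.89 ± 0.10 and 1.36 ± 0.11 on the log2 scale, FTL by 1.04 with the offsets, the quinone reductase gene NQO1 by 0.72 ± 0.13, a call lost by library totals (0.34) and without a low-count filter (0.41) that stood at 1.22 with the offsets, and the thioredoxin reductase gene TXNRD1 fell, with a change of -1.55 ± 0.13 (-0.86 with the offsets). The NRF2 list had 11 of 30 members higher and 4 lower, or 13 and 5 adjusted over the list alone, and did not pass its test (median 0.46, camera adjusted p = 0.29, fry adjusted p = 0.017). Aryl hydrocarbon receptor targets had 4 of 8 higher and 1 lower over all genes and adjusted over the list alone (median 0.64, or 0.41 without control replicate 1, camera adjusted p = 0.40, fry adjusted p = 0.0083), and with the offsets 5 higher and 2 lower (median 1.27). CYP1A1, a xenobiotic-metabolising enzyme, had a log2 change of 3.45 ± 0.93 (edgeR adjusted p = 0.015), which was lost without ZQ replicate 2 (1.83). ZQ replicates 1 to 3 held 5, 30 and 3 counts of CYP1A1, against a more even 375, 503 and 473 on olfactory receptor genes. CYP1A1 and CYP1A2, both among the higher members, held 11.1 and 6.96 ZQ counts per kb. Both lay under the 99th percentile of olfactory receptor genes (16.0) but above the 1.50 over those genes pooled, so background may account for part of their counts. CYP1B1 fell, with a change of -2.54 ± 0.34. Metallothionein and metal genes had 4 of 6 higher and 1 lower, or 4 and 2 adjusted over the list alone (median 1.59, camera adjusted p = 0.20, fry adjusted p = 0.0016), with MT2A up by 1.93 ± 0.15 on the log2 scale. With the offsets MT2A stood at 0.86 and the list had 2 higher, 0 lower and a median of 0.80. Heat shock genes had 5 of 21 higher and 5 lower over all genes and adjusted over the list alone (median -0.13, camera adjusted p = 0.63, lower by fry with adjusted p = 0.016). With the offsets 8 were higher and 4 lower, and the median was 0.07.

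Genes of cell division fell together: 26 of 33 G2/M genes were lower and 1 higher, with the same counts adjusted over the list alone, and the median was -1.61 (camera adjusted p = 1.7e-07, adjusted p = 0.13 with an estimated correlation). With the offsets 17 were lower and 1 higher, and the median was -1.01. ANLN, a cytokinesis scaffold, and the kinesin KIF20A fell with log2 changes of -3.40 ± 0.16 and -2.74 ± 0.19. DNA replication genes had 18 of 29 lower and 2 higher, or 19 and 2 adjusted over the list alone (median -1.25, camera adjusted p = 0.0016, adjusted p = 0.13 with an estimated correlation), with the ribonucleotide reductase subunit RRM1 at -1.82 ± 0.21 (-0.97 with the offsets). In cholesterol synthesis and uptake 14 of 25 genes were lower and 1 higher, or 15 and 1 adjusted over the list alone (median -1.69, camera adjusted p = 0.0016, adjusted p = 0.13 with an estimated correlation). INSIG1, a regulator of sterol synthesis, fell with a log2 change of -3.39 ± 0.27. Genes of hypoxia and glycolysis had 16 of 34 lower and 1 higher, or 17 and 1 adjusted over the list alone (median -0.73, camera adjusted p = 0.0029, adjusted p = 0.42 with an estimated correlation), with lactate dehydrogenase LDHA at -1.95 ± 0.14 (-1.09 with the offsets). Without control replicate 2 that list median was -0.46. Lysosome and autophagy genes had 15 of 35 lower and 4 higher, or 17 and 5 adjusted over the list alone (median -0.67, camera adjusted p = 0.032, adjusted p = 0.35 with an estimated correlation), with prosaposin PSAP at -2.94 ± 0.16.

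Matrix and protease genes had 16 of 32 lower and 5 higher over all genes and adjusted over the list alone (median -0.94, camera adjusted p = 0.011, adjusted p = 0.41 with an estimated correlation), and fibronectin FN1 fell with a log2 change of -3.25 ± 0.20. With the offsets the list median was -1.59, and the call ended with members of 1 list only. YAP targets had 9 of 24 lower and 2 higher over all genes and adjusted over the list alone (median -0.56, camera adjusted p = 0.026, adjusted p = 0.26 with an estimated correlation), with the matricellular gene CCN2 at -3.27 ± 0.29. Osmotic stress genes had 6 of 10 lower and 1 higher, or 7 and 1 adjusted over the list alone (median -1.71, camera adjusted p = 0.026, adjusted p = 0.26 with an estimated correlation), with the amino acid transporter SLC38A2 at -3.43 ± 0.15. The YAP call was lost in 7 of 20 alternatives, those without control replicate 1 and without control replicate 2 among them, and the osmotic call in 4 of 20, and with thinned controls the lysosome and autophagy call was lost as well. Among markers of other cell types, fibroblast genes had 5 of 9 lower and 0 higher, or 6 adjusted over the list alone (median -1.84, camera adjusted p = 0.0093, adjusted p = 0.18 with an estimated correlation), with THY1, a surface protein that these cells also express, at -1.84 ± 0.22 (-3.16 with the offsets). That call too ended with members of 1 list only. Endothelial genes had 3 of 6 higher and 0 lower, or 4 adjusted over the list alone (median 2.8, camera adjusted p = 0.026, adjusted p = 0.35 with an estimated correlation). That call ended in DESeq2 and with the GC and length offsets. The 3 were PECAM1, VWF and TIE1, with 2, 33 and 4 counts over the control libraries and 34, 62 and 48 over the ZQ libraries. At 4.38, 5.97 and 7.17 ZQ counts per kb all 3 lay under the 99th percentile of olfactory receptor genes, but above the 1.50 over those genes pooled. Background reads may account for part of the rise of this list.

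Transcripts of cytosolic ribosomal proteins rose, with 73 of 74 higher over all genes and adjusted over the list alone (median 1.33, camera adjusted p = 3.6e-19, adjusted p = 0.17 with an estimated correlation). With the offsets 59 were higher and 4 lower, and the median was 1.03. RPS2 rose by 2.11 ± 0.12 on the log2 scale (1.06 with the offsets), although many processed pseudogenes resemble these genes. Of 13 mitochondrially encoded mRNAs 12 were higher, or 13 adjusted over the list alone (median 2.57, camera adjusted p = 1.2e-07, adjusted p = 0.35 with an estimated correlation). MT-ND2, a complex I subunit, took 0.401% of counts in control and 6.24% in ZQ libraries, whereas the share of MT-CYB, a complex III subunit, was 1.91% and 1.92%. Nuclear copies of the mitochondrial genome can take such reads. Nuclear-encoded respiratory chain genes had 18 of 41 higher and 6 lower, or 19 and 6 adjusted over the list alone (median 0.50, camera adjusted p = 0.14). The list passed as higher in 7 of 20 alternatives, those without control replicate 1 and without control replicate 3 among them, and its median was 0.31 without ZQ replicate 1. With the offsets 9 were higher and 12 lower, and the median was -0.17. COX6B1 rose by 0.96 ± 0.15 on the log2 scale but stood at -0.02 with the GC and length offsets.

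The remaining lists did not pass camera as planned, although 30 lists passed without a low-count filter. In that setting the 38214 genes tested had a median log2 change of 1.75, so a list could pass as lower without falling. TGF-beta targets, fatty acid and lipid storage genes and replication-dependent histones were lower with the GC and length offsets (camera adjusted p = 0.010, 0.015 and 0.030, medians -0.50, -0.74 and -0.71). With an estimated correlation and the offsets their adjusted p was 0.14, 0.22 and 0.21. All 3 passed without a low-count filter, and the first 2 also in DESeq2 and by fry. TGF-beta targets had 3 of 26 higher and 12 lower (median -0.42, camera adjusted p = 0.11), and fatty acid and lipid storage genes 1 of 20 higher and 7 lower, or 1 and 8 adjusted over the list alone (median -0.49, camera adjusted p = 0.14). Junction and keratin genes had 3 of 20 higher and 8 lower, or 3 and 9 adjusted over the list alone (median -0.63, camera adjusted p = 0.45). Leaving out 1 library moved that median from -1.31 (without control replicate 3) to 0.32 (without ZQ replicate 3). Of its genes, vimentin VIM rose by 1.71 ± 0.12 on the log2 scale, and CDH1, the E-cadherin gene, was not tested at 6 control and 10 ZQ counts. Glucocorticoid targets had 3 of 15 higher and 5 lower, with a median of -0.40, or -0.70 without control replicate 1, and a mean of 0.39 (camera adjusted p = 0.70). Clock genes had 1 of 17 higher and 4 lower, or 1 and 2 adjusted over the list alone (median -1.03, camera adjusted p = 0.53, fry adjusted p = 0.031). The clock median was -0.12 with the offsets and -0.47 without control replicate 3. Glucose-responsive genes had 1 of 9 higher and 3 lower (median -0.05, or -0.71 with the offsets and also without ZQ replicate 2, camera adjusted p = 0.53), with TXNIP at -0.05. Targets of p53 had 2 of 25 higher and 4 lower, or 1 and 3 adjusted over the list alone (median -0.05, camera adjusted p = 0.69), and apoptosis regulators 1 of 23 higher and 3 lower (median -0.18, camera adjusted p = 0.53). Ribosome biogenesis genes had 8 of 30 higher and 5 lower (median 0.02, camera adjusted p = 0.70), a list that passed as lower without a low-count filter (median -0.28), and replication-dependent histones 0 of 13 higher and 1 lower (median -0.31, camera adjusted p = 0.63). Where no other count is given, that adjusted over the list alone was equal. Among lists too small to test, 2 of 2 small RNA genes were higher, 1 leukocyte gene was higher and 1 lower of 2, and 1 of 2 differentiated airway genes was higher, with equal counts adjusted over the list alone. The higher leukocyte and airway genes, CD74 and MUC5B, lay under the 99th percentile of olfactory receptor genes. So did HRK (apoptosis), MLXIPL (glucose-responsive), ZBTB16 (glucocorticoid) and NPAS2 (clock), counted as higher above, at 5.25, 3.12, 3.45 and 3.76 ZQ counts per kb. All of these lay above the 1.50 over olfactory receptor genes pooled.

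**Figure D5:**
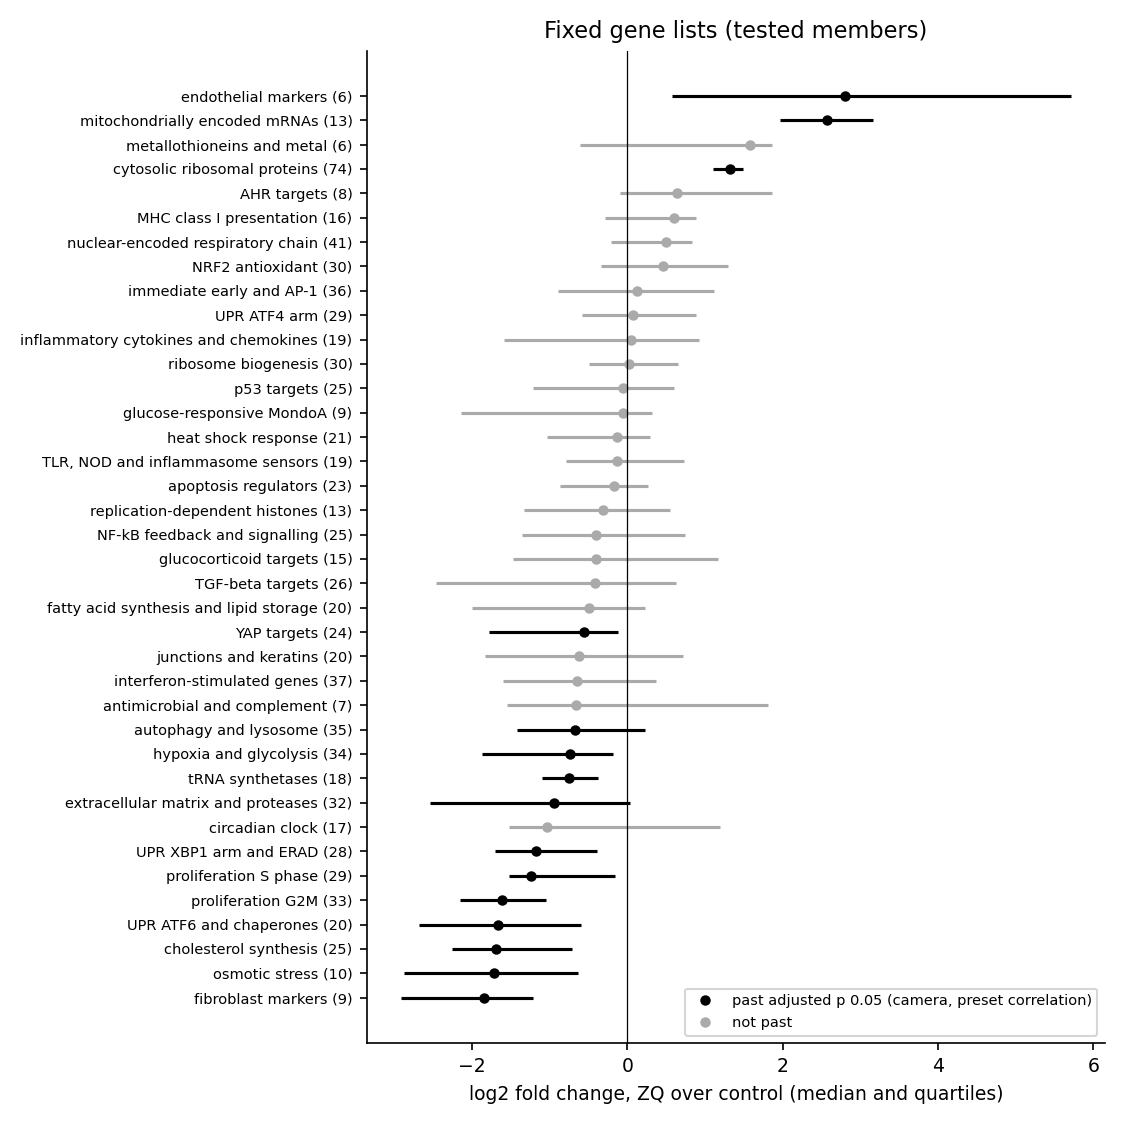
Median (point) and quartiles (line) of the log2 fold change of ZQ over control for the 38 gene lists tested, with the number of tested members in brackets; black marks lists past an adjusted p of 0.05 in camera with the preset correlation. Of the 38 lists 3 were higher and 12 lower, and 0 passed with an estimated correlation.

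Among single genes, MYCN, a MYC-family transcription factor, had 0 counts in control and 198 in ZQ libraries, at least 521-fold higher against a floor of 3 counts over the group. ZDHHC11B had 2 and 276 counts, a ratio of 1088 with a 95% counting interval of 298 to 9032. Of the other genes with the largest rises, CACNB4, MUC19, DNAH9, SLCO2A1 and ABCC8 had no control count and 86, 74, 67, 63 and 61 ZQ counts, at least 226-fold, 195-fold, 176-fold, 166-fold and 160-fold higher. Those 5 held 2.37 to 6.41 ZQ counts per kb, under the 99th percentile of olfactory receptor genes but 1.58 to 4.26 times their pooled density. Background reads may account for part of these counts. ENPP4 had 773 control counts and 0 with ZQ, at least 32.7-fold lower, and MIR155HG, the host transcript of an inflammatory microRNA, had 464 and 0, at least 19.6-fold lower. KIT, a receptor kinase, had 615 control counts and 1 ZQ count, 78.0-fold lower with an interval of 13.9 to 3085. The guidance and growth factor genes WNT5A and SEMA3A each had 3 ZQ counts against 1741 and 1639 in control cells, 73.6-fold and 69.3-fold lower with intervals of 25.1 to 357 and 23.7 to 336. ADAM9, a membrane metalloprotease, fell from 532 ± 25.9 to 13.1 ± 4.11 CPM (SD, n = 3 each), a log2 change of -5.34 ± 0.22 (edgeR adjusted p = 3.7e-07). Intervals and floors cover counting error only.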

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

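The 3 tests of thin background in this part were chosen after the values had been seen. Olfactory receptor genes, which airway epithelium is not known to use, stood out among genes left out of the gene tests. Over 376 such genes the ZQ libraries held 0.213 CPM per kb on average, by library totals without TMM factors, against 0.00422 in control libraries, a signal above the controls in data outside the main tests.

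This belongs to a wider pattern, counts in ZQ libraries on genes with no count in any control library. Lower depth argues the other way, since control libraries thinned to the ZQ depth had a mean of 15808 genes with a count against at least 23836 in ZQ libraries. A candidate source is reads spread thinly over the genome, such as DNA or unspliced RNA, and over all 381 olfactory receptor genes the density was 53.6 times that of control libraries. Of 4991 protein-coding genes without control counts, 0.421% (95% exact interval 0.261 to 0.642) lay above the 99th percentile of olfactory receptor genes, so as a set they carried no more than this background. MYCN and SAA1 had 76.1 and 477 ZQ counts per kb against 1.50 over the olfactory receptor genes, while CACNB4 and MUC19 had 2.37 and 2.51, and an effect of ZQ on any of them stays open and untested.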

How the results depend on the processing

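The GC and length offsets, thinned controls, weights per group and the filter of at least 5 CPM and 10 control counts were chosen after seeing the data. Over 186 named genes and 18 alternatives, 3162 of 3293 values kept direction and side of the threshold, 79 lost and 29 gained a call and 23 changed sign; over 38 lists and 20 alternatives the numbers were 665 of 759, 31, 34 and 29. The cause was not tested except where stated. Upper-quartile scaling gave 3767 genes higher and 1611 lower, and no low-count filter 11603 genes (7957 higher) and 30 lists. Without the filter 38214 genes were tested, with a median log2 change of 1.75, against which camera compares each list. An adjusted p under 0.01, stricter by construction, gave 3056 genes (1539 higher, 1517 lower), and the filter at 5 CPM 1654 higher. The number of lists was 0 with an estimated correlation, 26 by fry and 38 by fry for either direction. Leaving out 1 library gave 2815 to 5407 genes, 1389 to 2536 higher, 1426 to 2871 lower and 14 to 16 lists, with 2815 without control replicate 1 and 3055 without control replicate 3. With the replicate block 4404 genes (2032 higher, 2372 lower) and 15 lists passed, and IL6 stood at -0.016; same-numbered libraries correlated at 0.009, 0.037 and 0.032 in their deviations, under 0.1, so the numbers were not taken as pairs, although each library correlated best with its own number, a hint from the data and not the design. Signs changed as follows, with log2 changes for genes and, for lists, the median where the list test turned. TXNIP stood at 0.036 with RLE factors, 0.40 with upper-quartile scaling, 0.035 in DESeq2, 0.68 with the offsets and 0.16 with thinned controls. IL6 stood at -0.34 by library totals, -0.26 without a filter, -0.0011 in limma-voom and -0.0012 with weights per group. NFKBIA was 0.046 with upper-quartile scaling. With the offsets TRIB3 was -0.28, CCL20 0.21, ISG15 -0.37 and COX6B1 -0.016, and the list medians were 0.070 (ATF4 arm), -0.073 (class I presentation), -0.29 (immediate early), 0.067 (heat shock) and -0.17 (respiratory chain). Without a filter they were -0.18 (ATF4 arm), 0.29 (class I presentation), -0.18 (immediate early), 0.18 (NRF2), -0.28 (ribosome biogenesis) and 0.19 (respiratory chain), and by library totals -0.36 (ribosome biogenesis). DESeq2 gave -0.30 (NF-kB) and -0.055 (pattern recognition), thinned controls 0.0019 (NF-kB), 0.076 (pattern recognition), 0.12 (heat shock), -0.057 (p53) and 0.15 (histones), fry -0.65 (antimicrobial) and -0.40 (glucocorticoid), and members of 1 list only -0.42 (TGF-beta). Results whose sign or list test turned on leaving out 1 library ranged over those 6 fits as follows, with the library left out at each end in brackets: heat shock -0.35 to 0.026 (ZQ 1, control 1), TXNIP -0.83 to 0.27 (ZQ 2, control 2), NF-kB -0.69 to -0.15 (ZQ 3, control 2), p53 -0.24 to 0.28 (ZQ 3, control 1), IL6 -0.47 to 0.34 (ZQ 3, control 2), ribosome biogenesis -0.23 to 0.21 (ZQ 1, control 3), ATF4 arm -0.19 to 0.29 (ZQ 3, control 2), pattern recognition -0.30 to -0.023 (control 3, ZQ 1), immediate early -0.12 to 0.26 (ZQ 3, control 2), IL1A -0.78 to 0.87 (ZQ 3, ZQ 1). The medians of other lists that crossed 0 ran from -0.62 to 0.58 (inflammatory), -1.31 to 0.32 (junctions and keratins) and -0.84 to 0.24 (histones), with no turn of their list test.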

Other observations

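The tests on mitochondrial coverage, GC content, depth and membrane proteins in this part were chosen after the values had been seen; only the count of other splits was planned. Gene types outside the fixed lists were tabulated without a test of enrichment. Of 292 tested lincRNAs 116 were higher and 19 lower in edgeR, with a median log2 change of 1.34, and of 245 antisense transcripts 84 were higher and 10 lower, with a median of 1.19. Protein-coding genes had 2028 higher and 2391 lower of 11514 and a median of -0.06. Without a stated strand setting, antisense counts may hold reads of their partner genes, and the density of counts on olfactory receptor genes was 53.6 times that of control libraries. Of the higher lincRNAs 80 of 116, and of the higher antisense transcripts 59 of 84, lay no higher in ZQ counts per kb than the 99th percentile of olfactory receptor genes. These shares were not computed for all tested genes of the same types.

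Genes for secreted and membrane proteins outside the fixed lists were lower as a set. They were taken as the 1895 genes whose protein has a strongly hydrophobic segment, by mean hydropathy above 2.3 over 9 residues near the start or above 1.9 over 19 residues anywhere, limits chosen after others had been looked at, as was the minimum of 5 CPM. With the GC and length offsets 521 of them were lower and 147 higher in edgeR, against 1041 lower and 838 higher of 6424 genes without such a segment. Before the offsets the medians were -0.50 and -0.16, and with them -0.48 and -0.06.

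The fall of ER chaperone mRNAs was weighed against technical explanations. The list median was -1.70 after the GC and length offsets (camera adjusted p = 5.7e-07, range over alternatives 4.0e-11 to 0.13, adjusted p = 0.10 with the offsets and an estimated correlation) and -1.46 with controls thinned to the ZQ depth, so neither trend nor depth accounts for it as a whole. A general loss of mRNAs for secreted and membrane proteins may contribute, since genes with a hydrophobic segment differed from the others by -0.42 in median log2 change (95% bootstrap interval -0.51 to -0.36, resampling genes and not libraries). Random lists of such genes matched on mean expression had a median of -0.78 (95% between -1.46 and -0.17). The 19 chaperone genes scored there had a median of -1.73, at the 0.18 percentile of 10000 such lists. Those lists drew genes independently, while chaperone genes are induced together, so the percentile may be too small. Whether the general loss accounts for the whole fall was therefore not decided. Less ER stress with ZQ, and a change in cell state or RNA quality, stay open, because no uninfected or ZQ-only cells were analysed here.

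The larger mitochondrial share was weighed likewise. Mitochondrial DNA read evenly along its length could supply up to 9.94% of ZQ counts on the 13 mRNA genes, where the excess over control was 27.0%. The value of 9.94% rests on the lowest coverage of any of these genes of at least 500 bases. That length limit was set after the coverage had been seen. If reads of the gene with the lowest coverage were lost to nuclear copies, 9.94% is too low, so it may not be an upper bound. RNA from damaged or dying cells cannot be told apart from an effect of ZQ on live cells, since every ZQ library had the larger share, 4.53 times that of control libraries, and no measure of viability is among the data.

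The 6 libraries can be split into 3 against 3 in 10 ways, too few for a share under 0.05. The real split was the 1 with the most calls, giving 4978 genes against at most 0 in the other splits (edgeR), and the same 1 split led for genes higher (2506) and lower (2472). Every other split mixed control and ZQ libraries in both groups, which turns the group difference into spread within groups. Few gene calls were bound to follow there, so this contrast cannot decide about chance. For fixed lists 1 split reached 15, and the highest of the others gave 8.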
